A study of Anser cygnoides with 12 samples.

How the data were processed

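Poly(A) RNA from the ileum of Yangzhou geese was sequenced in 12 libraries, 4 for each of 3 diets. Per the labels, the libraries came from a strand-specific kit and were read as pairs of 150 bases on a NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR. They give no order or role for these tools, and the genome build and the annotation version are not given in the sources used here. Whether counting used the strand, and how reads shared between near-identical gene copies were treated, is not given either. Levels of overlapping genes, antisense partners and close paralogs are uncertain for that reason.

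The authors deposited a table with a raw count and an FPKM value for each gene in each library, per the file headers. FPKM is the authors' scaling of a count to transcript length and library size. The ratio of count to FPKM was constant across libraries within 1% for 99.3% of the 11582 genes checked. The table held 19836 genes on 860 scaffolds, no line without a gene name and 0 columns of other samples. The smallest counts clustered at 4 (5063 times), against 1799 times at 3 and 1526 times at 5, so that 1 read pair stands for about 4 counts. Counting error is therefore larger than the counts alone would give, and floors cover neither all of it nor the spread between samples. Total counts ranged from 38706155 to 48251825 per library. A floor of 3 counts per library was used for genes at 0. It lies below the about 4 counts of 1 read pair, so folds against it are not lower bounds.

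Groups were taken from the sample titles and diet labels. Nothing in the labels says whether replicates are separate birds, so p-values measure the spread between these samples. Gene identifiers were matched to a table of gene names of another goose assembly. Of the identifiers, 17685 matched and 2151 did not, and 687 of the 7268 genes with a LOC name received a symbol from it. Positions are printed as the deposited table gives them, on its scaffolds. No coordinate of that assembly is printed.

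The design was fixed before the data were examined, together with 44 gene lists (27 pathways and 17 cell type or position markers), the rule for named genes and the alternatives to be tried. It foresaw a file of FPKM values and limma on log2(FPKM + 1), with edgeR in its place if the file held raw counts. The file held counts, so edgeR was used as that design allowed. The main test was edgeR's quasi-likelihood test with TMM scaling and filterByExpr (minimum count 10) on all 12 libraries, with the diet as the only term and 9 residual degrees of freedom. It was two-sided, with Benjamini-Hochberg adjustment over the 16075 genes tested and a threshold of 0.05. Fold changes are fitted with a prior count and printed as log2 values with standard errors. Each standard error is the absolute log2 fold change divided by the square root of its quasi-likelihood F, and was not estimated separately.

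Gene lists with at least 5 tested members, 43 of the 44, were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera compares a list with all other genes. It was repeated with an estimated correlation, and fry tested whether a list's genes moved one way on balance. A list score is the mean over members of log2 CPM after centring each gene over the 12 libraries. Scores were compared by exact two-sided permutation tests over all 70 arrangements of 8 libraries, adjusted over the 43 lists. The smallest p this design can give is 0.0286.

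The rule for named genes took, per direction, called genes with the largest change and, where fewer than 5 were called, the 3 symbols with the smallest p. It added up to 4 members with the smallest p of every called list, members past the threshold of their list, and 16 genes named whatever their values. After values were seen, the number per called list was set to 2 beyond those past the list's threshold. This also sets which genes the search for outlying libraries covers. Of the genes named by this rule, 2 are not reported here: that search leaves them out, while list tests and counts of values over named genes include them. Of the 16 genes, PNP was in the table but not tested, and IL1B was not among its names.

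The code was tested on simulated counts drawn from the means and library sizes of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. At 2-fold it recovered 43 genes for high protein against control, 42 for lactulose against high protein and 46 for lactulose against control, and at 4-fold 87, 90 and 86. It also called 9 of 15554, 8 of 15532 and 3 of 15542 unchanged genes. A list lowered 1.5-fold was called by all 3 list tests, and 0 of 42 other lists were called. The simulated genes were drawn independently of each other. This count therefore gives no rate of false calls for lists whose genes vary together.

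Alternatives chosen at that time were another scaling, filters, FPKM values with limma, quantile normalization, sample weights, only the groups compared, the replicate number as a block, DESeq2, fold thresholds and leaving out each library in turn. Chosen after seeing the data were counts divided by 4, lactulose 3 and 5 counted as 1 library, and leaving out the libraries in doubt, control 3 and lactulose 3. So were a score of 18 genes that the other assembly places on the W chromosome or of the enterocyte list as a covariate, and limma on log2(FPKM + 1). The design foresaw the last as the main test of a file of FPKM values, and not as an alternative. These 18 were picked for levels spanning over 5 log2 units, and not all of them vary alike between libraries. The 2 count classes used to compare lactulose 3 with lactulose 5 (20 to 300 counts, and above 10000) were also set after seeing the data. Reads and isoforms were not analysed here.

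Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.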

Results

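Gene expression was measured in the ileum, the last segment of the small intestine, of Yangzhou geese, a domestic goose breed, on 3 diets. Control geese received a basal diet with 18% crude protein, high protein geese a diet with 21%, and lactulose geese the 21% diet with 0.3% lactulose, a synthetic disaccharide that the host does not digest and gut bacteria ferment. Each diet had 4 libraries, numbered here as in the labels. Total counts were 48251825, 45247547, 38706155 and 41874570 in control 3, 4, 6 and 7, and 46148575, 43898114, 43652234 and 42073193 in high protein 1, 3, 4 and 5. They were 39584113, 45944497, 41922052 and 41182328 in lactulose 2, 3, 5 and 6. Between 16947 and 17492 of the 19836 genes had counts above 0 in a library. EEF1A1, a translation elongation factor, was the most abundant gene in each library, with 1.42 to 4.18% of the counts. The common biological coefficient of variation was 0.349.

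Some libraries stood apart within their groups. Control 3 had the lowest median correlation with the others (0.957, against 0.972 to 0.980), and its 20 most abundant genes held 13.9% of its counts, against 8.18 to 12.8% elsewhere. Lactulose 3 and 5 correlated at 0.996 across genes. Their squared difference per count was 6.82, as a median divided by the chi-square median so that it estimates a mean. On that scale the 17 other pairs within groups had 24.2 to 160, and read-pair noise is about 4. Above 10000 counts lactulose 3 and 5 had 37.2, above that noise and far below the 336 to 3764 of the other pairs. Whether they are separate samples is open, and both were kept as the labels give them. Enterocyte genes, which mark the absorptive epithelium, varied within each group. Their mean level was 6.93 to 8.40 log2 CPM in controls, 6.90 to 8.43 with high protein and 7.07 to 8.75 with lactulose.

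The first comparison asked what the higher protein diet did to the ileum relative to the basal diet. Genes of macrophages and dendritic cells and of smooth muscle were higher as groups with high protein, by medians of 0.24 and 0.34 on the log2 scale, and cell cycle and immediate early genes were lower, by −0.22 and −0.25. These calls did not hold with an estimated correlation between genes (adjusted p = 0.391, 0.848, 0.882 and 0.391 in that order, by camera). Among single genes, ISX, a homeobox transcription factor of the intestinal epithelium, stood at 9.35 ± 0.579 FPKM with high protein and 26.8 ± 7.91 FPKM in controls (mean ± SD, n = 4 per group here and throughout). SCARB1, a receptor for high-density lipoprotein, stood at 33.9 ± 27.6 against 5.05 ± 1.85 FPKM. Neither passed edgeR over all genes, while DESeq2 called both.

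The ISX gene (ID 106035778) lies at 207817 to 234454 on scaffold NW_025927850.1, and its log2 fold change was −1.58 ± 0.26 (SE; edgeR adjusted p = 0.341). Without control 6 that adjusted p was 0.00724, within a range over the alternatives of 3.6e-05 to 1.0. SCARB1 (ID 106031181; NW_025927732.1, 781410 to 797643) had a log2 fold change of 2.80 ± 0.57. The other genes of smallest p were C1QA and MAPRE3, which were higher, and EFR3B and CP, which were lower. C1QA (ID 106040121; NW_025927702.1, 186110 to 188520), a chain of complement C1q made by macrophages, stood at 101 ± 14.9 against 66.5 ± 9.999 FPKM. MAPRE3 (ID 106049318; NW_025927977.1, 276 to 6629), which binds growing microtubule ends, stood at 10.3 ± 1.24 against 6.90 ± 1.42 FPKM. EFR3B (ID 106038181; NW_025927776.1, 2492790 to 2534177) stood at 1.08 ± 0.163 against 2.03 ± 0.473 FPKM. CP (ID 106047684; NW_025927675.1, 9494290 to 9513999), the copper-carrying ferroxidase ceruloplasmin, stood at 9.23 ± 2.002 against 16.1 ± 4.65 FPKM. Adjusted p was 1.0 for SCARB1 and these 4 genes by edgeR. Over the alternatives the lowest adjusted p was 0.000256 for SCARB1, 0.0166 for EFR3B and 0.0269 for MAPRE3, which DESeq2 called, and 0.0509 for C1QA and 0.102 for CP, which no alternative called, and the highest was 1.0 for each.

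Over all genes tested, edgeR's quasi-likelihood test called 0 of 16075 genes, with 510 at an unadjusted p under 0.05 (211 higher, 299 lower). DESeq2 called 8 (5 higher, 3 lower), limma on log2 FPKM called 1 with either pseudocount, and edgeR called 1 without a filter, 1 without control 6 (ISX) and 1 without high protein 5. The smallest edgeR adjusted p, 0.0522, was that of LOC125183064, a long non-coding RNA named after its values were seen, which DESeq2 also called and which was the 1 gene of limma, of edgeR without a filter and without high protein 5. It had 0 counts in all controls and 74 to 387 counts in the 8 other libraries.

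Of 43 gene lists, 9 were called, 6 higher and 3 lower with high protein. With an estimated correlation between genes, 0 were called. The macrophage and dendritic cell list rose (adjusted p = 7.9e-07), with 19 of 22 members positive (adjusted p = 0.391 with an estimated correlation). C1QA rose adjusted over the list alone, 1 of 22, and CYBB, the NADPH oxidase subunit of phagocytes, stood at 8.67 ± 1.497 against 6.68 ± 1.97 FPKM. Smooth muscle genes rose (adjusted p = 4.5e-07), with 20 of 20 members positive (adjusted p = 0.848 with an estimated correlation), and 0 passed adjusted over the list alone. Among them, LMOD1, an actin filament nucleator of smooth muscle, stood at 22.5 ± 6.96 against 15.1 ± 6.27 FPKM, and SMTN at 202 ± 58.5 against 141 ± 68.5 FPKM. The smooth muscle median was 0.58 without control 6 and 0.21 without high protein 5.

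The cell cycle list fell (adjusted p = 4.5e-07), with 59 of 64 members negative (adjusted p = 0.882 with an estimated correlation) and 0 past the threshold adjusted over the list alone. CDC45, needed to start DNA replication, stood at 2.098 ± 0.568 against 3.07 ± 0.745 FPKM, and the spindle checkpoint kinase BUB1 at 7.59 ± 1.34 against 10.2 ± 2.49 FPKM. Leaving out high protein 3 ended this call (median −0.08, adjusted p = 0.0847), and the median was −0.12 without control 7. Immediate early genes, which cells switch on within minutes of a stimulus, fell (adjusted p = 7.9e-05), with 25 of 28 members negative (adjusted p = 0.391 with an estimated correlation). SIK1, a kinase induced by cyclic AMP, fell adjusted over the list alone, from 14.3 ± 2.096 to 9.13 ± 1.16 FPKM. JUN, a subunit of the AP-1 transcription factor, stood at 66.9 ± 6.73 against 85.7 ± 14.2 FPKM.

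Of the other 5 called lists, the endothelium list rose (17 members, median 0.21, adjusted p = 0.0033; adjusted p = 0.882 with an estimated correlation). Its vascular receptors FLT1 and TEK had log2 fold changes of 0.91 ± 0.30 and 0.74 ± 0.32. B and plasma cell genes fell (18 members, median −0.26, adjusted p = 0.017; adjusted p = 0.848 with an estimated correlation), with BCL6, a transcriptional repressor of germinal centre B cells, at −0.50 ± 0.14. Heat shock genes rose (21 of 23 members positive, median 0.14, adjusted p = 0.017; adjusted p = 0.882 with an estimated correlation), with HSF1 and CHORDC1 at 0.22 ± 0.13 and 0.18 ± 0.13. Markers of the proximal small intestine rose (14 members, median 0.52, adjusted p = 0.027; adjusted p = 0.848 with an estimated correlation). Collagen and matrix genes rose (25 of 35 members positive, median 0.10, adjusted p = 0.029; adjusted p = 0.959 with an estimated correlation), with LAMA4 and NID1 at 0.34 ± 0.25 and 0.27 ± 0.21. In each of these lists 0 members passed adjusted over the list alone. The proximal list held GATA4, a transcription factor of the proximal gut, at 0 in all controls. With high protein GATA4 stood 94.8-fold above a floor of 3 counts per library, which is no lower bound. Almost all of this came from high protein 1 with 1166 counts. The list also held lactase, LCT, at 2.02 ± 3.26 against 0.256 ± 0.122 FPKM, with 6.91 FPKM in high protein 1. The list was not called by limma on log2 FPKM (medians 0.13 and 0.12) or with counts divided by 4 (0.32). With GATA4 set to its fold against the floor, the list median stayed 0.52 and the mean was 1.38 in place of 1.71.

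Single libraries decided several of these calls. Endothelium was not called without control 3 (median 0.10) or high protein 3 (−0.01), and its median was 0.46 without control 6 and 0.32 without high protein 4. Heat shock was not called without control 3 (0.06), control 4 (0.11) or high protein 5 (0.05), and stood at 0.23 without control 6. B and plasma cell genes were not called without control 4, 6 or 7 or high protein 1 or 5 (medians −0.26 to −0.16). The proximal list was not called without control 4 (0.43), control 6 (0.57) or high protein 1 (0.48), and stood at 0.83 without control 3. Collagen and matrix genes turned to −0.12 without control 3 and to −0.03 without high protein 3, and were not called without control 4 (0.06) or high protein 1 (0.11) or 5 (0.11). Their median was 0.28 without control 6, 0.19 without control 7 and 0.18 without high protein 4.

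The second comparison asked what lactulose did on the high protein diet. Cytosolic ribosomal protein genes and oxidative phosphorylation genes were lower with lactulose, by medians of −0.78 and −0.34 on the log2 scale, calls that did not hold with an estimated correlation (adjusted p = 0.410 and 0.640 by camera). Macrophage and dendritic cell genes were lower by −0.38 and T and NK cell genes by −0.31, and immediate early genes were higher by 0.49 (adjusted p = 0.0894, 0.614 and 0.0645 with an estimated correlation). The gene of smallest p was HAAO, an enzyme of tryptophan breakdown in the kynurenine pathway, at 2.44 ± 0.348 FPKM with lactulose and 5.02 ± 1.12 with high protein. CEL, a lipase activated by bile salts, stood at 4.95 ± 1.32 against 12.9 ± 0.621 FPKM.

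HAAO (ID 106031489; NW_025927670.1, 3219731 to 3254064) had a log2 fold change of −1.12 ± 0.19 (SE), and CEL (ID 106029666; NW_025927668.1, 7669600 to 7683690) one of −1.49 ± 0.26, both with an edgeR adjusted p of 0.572. Over the alternatives, adjusted p ranged from 8.0e-06 to 1.0 for HAAO and from 0.000312 to 1.0 for CEL, with 0.0173 without control 7. C1QA stood at 66.8 ± 12.1 against 101 ± 14.9 FPKM (adjusted p = 0.680 by edgeR), close to its control level of 66.5 FPKM. Among higher genes, NMRAL1 (ID 106033404; NW_025927663.1, 4872354 to 4876491) stood at 8.23 ± 2.06 against 3.39 ± 0.495 FPKM. ASAP3 (ID 106045118; NW_025927729.1, 3140209 to 3157125), a GTPase-activating protein for Arf proteins, stood at 15.5 ± 0.737 against 9.49 ± 0.857 FPKM. ADRA2A (ID 106031945; NW_025927678.1, 5986798 to 6012878), an adrenergic receptor, stood at 0.649 ± 0.269 against 0.203 ± 0.0778 FPKM, and at no more than 0.903 FPKM in any library. None of these higher genes passed edgeR over all genes. Over the alternatives their lowest adjusted p, by DESeq2, was 0.00559 for NMRAL1, 0.00369 for ASAP3 and 0.0081 for ADRA2A.

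Here edgeR called 0 of 16075 genes, with 908 at an unadjusted p under 0.05 (372 higher, 536 lower). DESeq2 called 19 (10 higher, 9 lower), limma on log2 FPKM called 0, edgeR called 1, CEL, without control 7, and limma with sample weights, which gave lactulose 3 and 5 the largest weights, called 513 (129 higher, 384 lower).

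Of 43 lists, 16 were called, 7 higher and 9 lower with lactulose. Camera called 0 with an estimated correlation, and fry called 2, immediate early genes and macrophage and dendritic cell genes, each with an adjusted p of 0.0414. Ribosomal protein genes fell (adjusted p = 1.5e-33), with 70 of 70 members negative (adjusted p = 0.410 with an estimated correlation) and 0 past the threshold adjusted over the list alone. RPL35A stood at 635 ± 175 against 1332 ± 328 FPKM and RPL3 at 769 ± 185 against 1235 ± 132 FPKM. Oxidative phosphorylation genes fell (adjusted p = 3.5e-10), with 59 of 63 negative (adjusted p = 0.640 with an estimated correlation) and 0 past the threshold adjusted over the list alone. The complex I subunits NDUFV2 and NDUFA10 stood at 98.8 ± 20.4 against 165 ± 26.6 and at 135 ± 27.2 against 196 ± 29.0 FPKM.

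Macrophage and dendritic cell genes fell (adjusted p = 7.7e-10), with 19 of 22 negative (adjusted p = 0.0894 with an estimated correlation), and 4 fell adjusted over the list alone, against 0 over all genes by edgeR. Over the alternatives, at least 1 called C1QA, SPI1 and CD83 over all genes, with lowest adjusted p of 0.00444, 0.0123 and 0.0442, and the highest was 1.0 for each. The 4 were C1QA, the myeloid transcription factor SPI1 (43.5 ± 5.32 to 31.1 ± 4.63 FPKM), the dendritic cell surface protein CD83 (15.7 ± 3.31 to 10.9 ± 1.82 FPKM) and LY96, the partner of TLR4 in lipopolysaccharide sensing (1.85 ± 0.555 to 1.16 ± 0.104 FPKM). T and NK cell genes fell (adjusted p = 2.0e-06), with 24 of 28 negative (adjusted p = 0.614 with an estimated correlation), and the median was −0.11 without high protein 4. CD4, the helper T cell coreceptor, fell adjusted over the list alone, from 14.7 ± 1.30 to 9.38 ± 0.656 FPKM, and CD28 stood at 3.57 ± 0.508 against 5.07 ± 0.784 FPKM. TLR, NF-kB and cytokine genes fell (adjusted p = 5.8e-05), with 32 of 44 negative and a median of −0.19 (adjusted p = 0.406 with an estimated correlation), and 0 passed adjusted over the list alone. CCL20, a chemokine for cells bearing CCR6, stood at 20.1 ± 4.21 against 46.6 ± 12.6 FPKM. That median was −0.11 without lactulose 2.

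Immediate early genes rose (adjusted p = 8.2e-11), with 25 of 28 positive (adjusted p = 0.0645 with an estimated correlation). Adjusted over the list alone 6 rose, against 0 over all genes by edgeR, while 1 alternative each called BTG2 and NR4A1 (lowest adjusted p 0.0276 and 0.0374, highest 1.0). The 6 were the AP-1 subunits FOS (5.41 ± 1.75 to 19.0 ± 15.0 FPKM) and JUN (66.9 ± 6.73 to 105 ± 29.0 FPKM), the nuclear receptor NR4A1 (1.48 ± 0.460 to 3.53 ± 1.17 FPKM), the antiproliferative BTG2 (52.8 ± 9.94 to 101 ± 15.1 FPKM), the phosphatase DUSP1 (38.2 ± 4.95 to 68.0 ± 25.4 FPKM) and SIK1 (9.13 ± 1.16 to 13.4 ± 1.73 FPKM). In lactulose 2 and 6 FOS stood at 22.9 and 38.5 and DUSP1 at 95.2 and 84.2 FPKM, against 8.90 and 5.57 and 47.3 and 45.4 FPKM in lactulose 3 and 5. The circadian clock list rose (18 members, median 0.18, adjusted p = 0.012; adjusted p = 0.406 with an estimated correlation), and 2 rose adjusted over the list alone. These were the period genes PER2 (17.8 ± 2.45 to 30.1 ± 6.74 FPKM) and PER3 (1.904 ± 0.519 to 3.32 ± 0.536 FPKM). The clock list was not called without high protein 4 (median 0.14) or lactulose 5 (0.16).

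Enteroendocrine cell genes, the hormone-producing cells of the epithelium, rose (15 of 17 positive, median 0.38, adjusted p = 0.0013; adjusted p = 0.406 with an estimated correlation), and their median was 0.24 without lactulose 5. The secretogranins SCG2 and SCG3 stood at 17.9 ± 3.85 against 11.7 ± 2.47 and at 12.2 ± 1.66 against 8.27 ± 2.66 FPKM. Enteric neuron and glia genes rose (19 of 22 positive, median 0.44, adjusted p = 0.0017; adjusted p = 0.640 with an estimated correlation), with GFRA3 and ERBB3 at log2 fold changes of 0.61 ± 0.30 and 0.41 ± 0.20. That list was not called without high protein 4 (0.29) or lactulose 2 (0.19), nor by limma on log2 FPKM (0.34 and 0.22). De novo purine synthesis genes, which build the purines that birds break down to uric acid, fell (13 of 14 negative, median −0.18, adjusted p = 0.0038; adjusted p = 0.406 with an estimated correlation). GMPS stood at 23.8 ± 0.709 against 26.9 ± 2.46 and MTHFD2 at 13.8 ± 1.42 against 16.5 ± 2.53 FPKM. The purine median was −0.30 without lactulose 2, −0.11 without lactulose 3 and −0.11 without lactulose 5. In these 3 lists 0 members passed adjusted over the list alone.

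Peptide and amino acid absorption genes rose (28 of 33 positive, median 0.26, adjusted p = 0.012; adjusted p = 0.640 with an estimated correlation). SLC1A1, a transporter of acidic amino acids, stood at 295 ± 228 against 115 ± 51.7 FPKM and SLC38A1 at 7.63 ± 1.77 against 5.55 ± 0.698 FPKM. Ileal bile acid handling genes rose (11 of 13 positive, median 0.40, adjusted p = 0.043; adjusted p = 0.788 with an estimated correlation). Among them the ileal bile acid transporter SLC10A2 stood at 84.6 ± 63.5 against 30.2 ± 19.3 FPKM, and ABCB11 at 0.352 ± 0.311 against 0.0703 ± 0.0212 FPKM. In lactulose 3 and 5 SLC1A1 stood at 466 and 517 and SLC10A2 at 132 and 146 FPKM, against 91.1 and 104 and 20.9 and 39.5 FPKM in lactulose 2 and 6. Junction genes rose (20 of 27 positive, median 0.15, adjusted p = 0.043; adjusted p = 0.640 with an estimated correlation), with TJP3 and PARD3 at log2 fold changes of 0.57 ± 0.24 and 0.23 ± 0.12. In these lists 0 members passed adjusted over the list alone. With the enterocyte level as a covariate, peptide absorption had a median of 0.16 (adjusted p = 0.0670) and bile acid handling 0.05 (adjusted p = 0.219), and neither was called. Peptide absorption was not called without high protein 3 (0.23) or lactulose 3 (0.17) or 5 (0.11), and stood at 0.40 without lactulose 6. Bile acid handling was not called without high protein 3 (0.14) or 4 (0.36) or lactulose 3 (0.18) or 5 (0.09), and stood at 0.72 without lactulose 2 and 0.61 without lactulose 6. Junction genes were not called without high protein 3 (0.10) or 4 (0.16) or lactulose 3 (0.09) or 5 (0.08), and stood at 0.23 without high protein 1.

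Apoptosis genes fell (23 of 32 negative, median −0.16, adjusted p = 0.018; adjusted p = 0.640 with an estimated correlation), with BCL2L15 at −0.80 ± 0.40. Cell cycle genes fell (41 of 64 negative, median −0.08, adjusted p = 0.019; adjusted p = 0.796 with an estimated correlation), with CENPK and TK1 at −0.63 ± 0.23 and −0.49 ± 0.20. Antioxidant genes fell (30 of 39 negative, median −0.13, adjusted p = 0.019; adjusted p = 0.689 with an estimated correlation), with NQO2 and GPX8 at −0.73 ± 0.31 and −0.61 ± 0.35. In these lists 0 members passed adjusted over the list alone. Apoptosis was not called without high protein 4 (−0.11) or lactulose 2 (−0.15) or 6 (−0.13), and antioxidant genes not without high protein 1 (−0.09) or lactulose 2 (−0.03). Cell cycle genes were not called without high protein 1 or 4 or lactulose 3, 5 or 6 (medians −0.04 to 0.00), and stood at −0.23 without high protein 3 and −0.25 without lactulose 2.

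**Figure D1:**
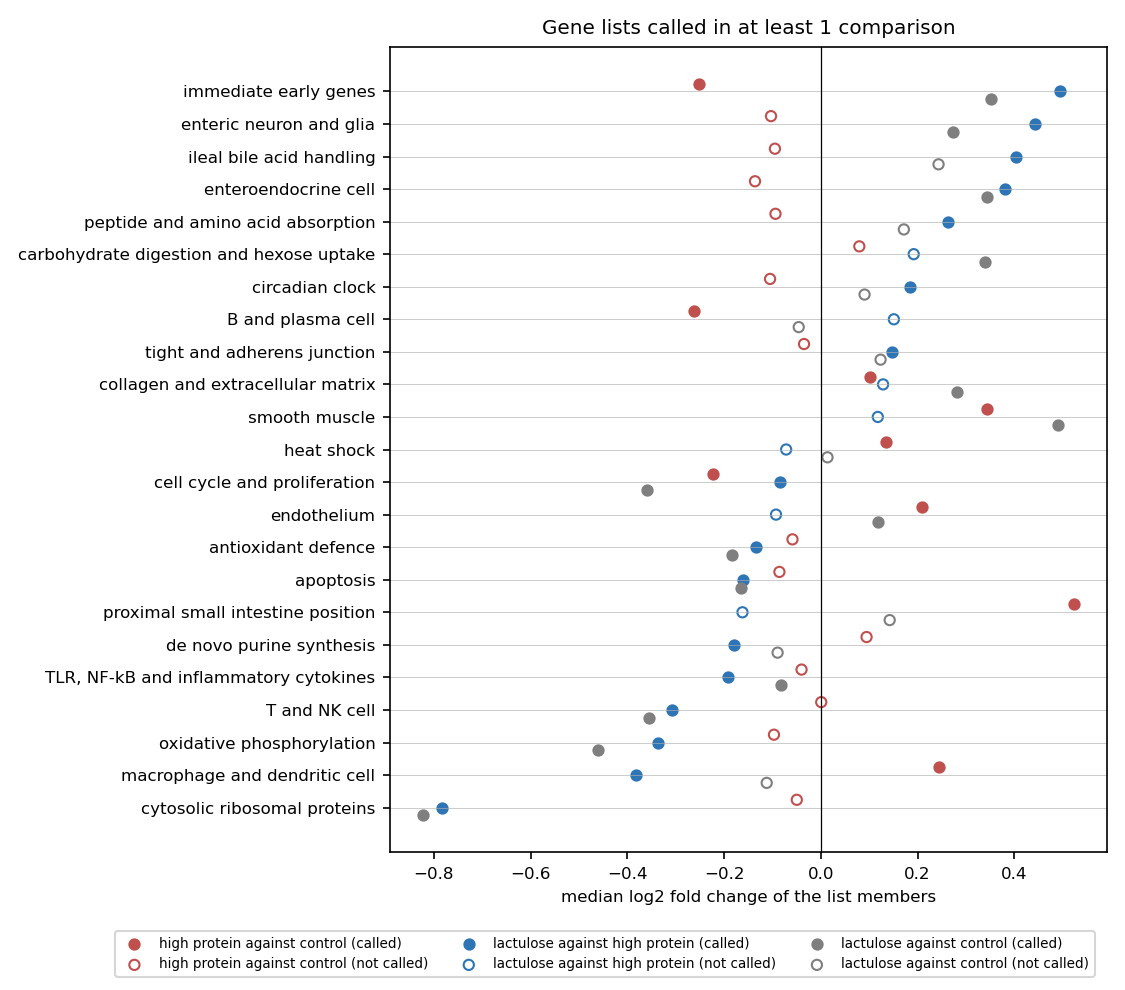
Median log2 fold change (horizontal axis) of each of the 23 gene lists called in at least 1 of the 3 comparisons, with 1 color per comparison, filled circles for called lists and open circles for others. Ribosomal protein genes lie lowest, at −0.78 for lactulose against high protein and −0.82 for lactulose against control.

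**Figure D2:**
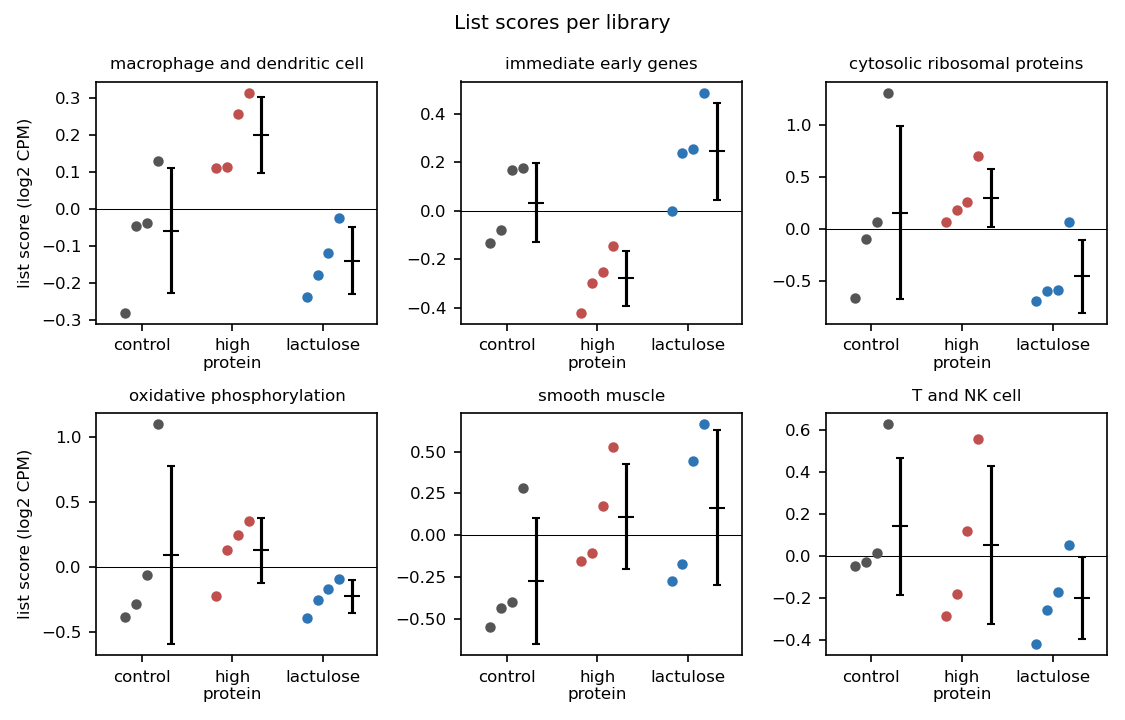
Score of 6 gene lists in each library (vertical axis, mean centred log2 CPM of the members), as points sorted by value within each diet, with a bar for the mean ± SD of 4 libraries. Macrophage and dendritic cell scores average 0.20 with high protein and −0.14 with lactulose, with no overlap between these groups.

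Per library, list scores separated the groups rarely. Groups did not overlap for 1 of 43 lists in high protein against control, 2 in lactulose against high protein and 0 in lactulose against control, where chance gives 2.86% of lists. Immediate early scores were 0.03 ± 0.16 in controls, −0.28 ± 0.11 with high protein and 0.24 ± 0.20 with lactulose, and macrophage and dendritic cell scores were −0.06 ± 0.17, 0.20 ± 0.10 and −0.14 ± 0.09. The exact permutation p was 0.0286, the smallest possible, for immediate early scores in the first comparison and for both lists in the second. Adjusted over the 43 lists these exact values were 0.971 and 0.527, so none passed. Ribosomal protein scores were 0.16 ± 0.83, 0.30 ± 0.28 and −0.46 ± 0.35, with 1.31 in control 3.

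**Figure D3:**
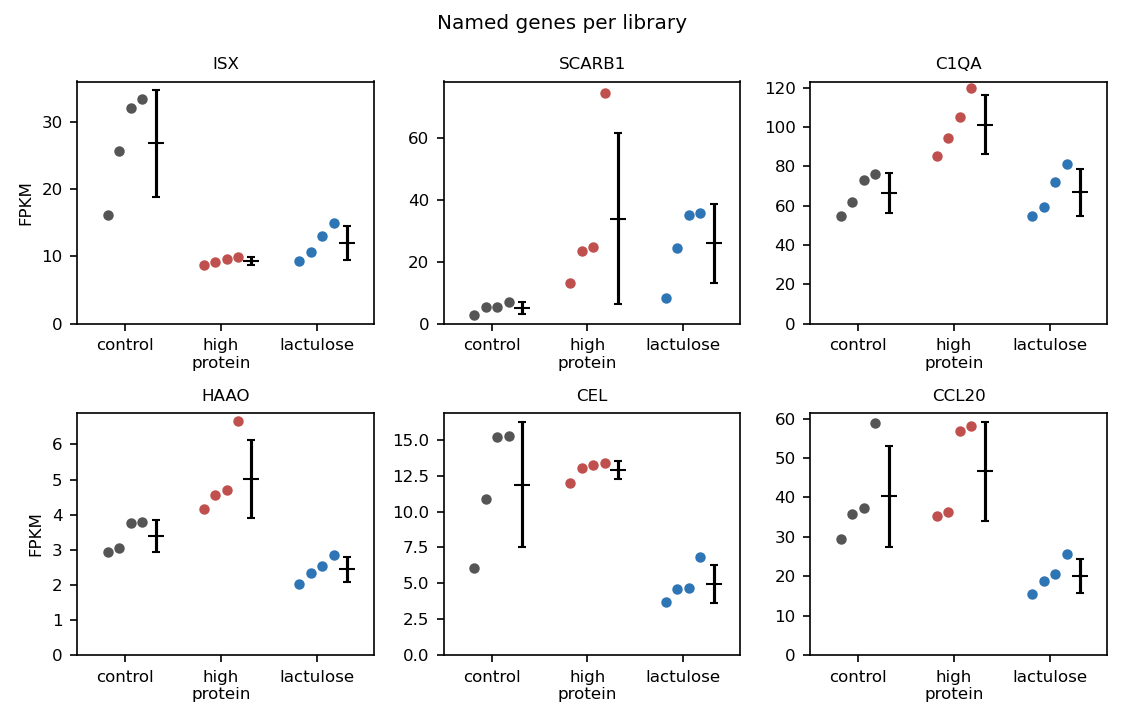
FPKM (vertical axis) of ISX, SCARB1, C1QA, HAAO, CEL and CCL20 in each library, as points sorted by value within each diet, with a bar for the mean ± SD of 4 libraries. ISX averages 26.8 FPKM in controls, 9.35 with high protein and 11.98 with lactulose.

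The third comparison set the lactulose diet against the basal diet, so that crude protein and lactulose differ together. Ribosomal protein, oxidative phosphorylation, cell cycle and T and NK cell genes were lower, by medians of −0.82, −0.46, −0.36 and −0.36, and smooth muscle genes were higher by 0.49. With an estimated correlation adjusted p was 0.598 to 0.687 for these lists by camera, and without control 3 the first 2 medians were −0.23 and −0.02. ISX stood at 11.98 ± 2.499 FPKM against 26.8 ± 7.91, and CEL at 4.95 ± 1.32 against 11.9 ± 4.37. CHGA, the chromogranin of enteroendocrine granules, stood at 249 ± 42.5 against 129 ± 46.9 FPKM.

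The log2 fold change was −1.33 ± 0.26 for ISX and −1.37 ± 0.26 for CEL, both with an adjusted p of 0.725 by edgeR. Without control 6 the adjusted p of ISX was 0.0340, within a range over the alternatives of 0.00385 to 0.999, and without control 7 that of CEL was 0.0148, within 0.00262 to 0.999. WDR31 (ID 106037113; NW_025927668.1, 1528703 to 1540548) stood at 4.83 ± 0.281 against 6.89 ± 0.865 FPKM. Higher genes were the calcium channel subunit CACNA1E (ID 106047781; NW_025928011.1, 227671 to 339173) at 3.14 ± 0.905 against 1.62 ± 0.265 FPKM and the ATP-gated channel P2RX1 (ID 106041500; NW_025927704.1, 3443632 to 3455665) at 47.2 ± 5.30 against 28.4 ± 8.32 FPKM. PTPRK (ID 106032487; NW_025927694.1, 28594 to 260152), a receptor tyrosine phosphatase, stood at 11.8 ± 1.23 against 8.05 ± 1.70 FPKM. In this comparison edgeR called 0 of 16075 genes, with 997 at an unadjusted p under 0.05 (364 higher, 633 lower) and a smallest adjusted p of 0.0735 for LOC125183064. DESeq2 called 22 (13 higher, 9 lower), limma on log2 FPKM 1 with either pseudocount (LOC125183064), and edgeR 1 without a filter, 1 without control 6, 1 without control 7 and 1 without high protein 5.

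Of 43 lists, 14 were called, 7 higher and 7 lower, and 0 with an estimated correlation or by fry. Ribosomal protein genes fell (70 of 70 negative, adjusted p = 1.2e-23; adjusted p = 0.598 with an estimated correlation), with RPL35A at 635 ± 175 against 1311 ± 615 FPKM and RPS27A at 1058 ± 349 against 1801 ± 691 FPKM. Their median was −0.23 without control 3. Oxidative phosphorylation genes fell (59 of 63 negative, adjusted p = 6.2e-10; adjusted p = 0.687 with an estimated correlation), with NDUFV2 and NDUFA7 at −0.95 ± 0.34 and −0.96 ± 0.37. That call ended without control 3 (median −0.02). Antioxidant genes fell (30 of 39 negative, median −0.18, adjusted p = 0.0077; adjusted p = 0.687 with an estimated correlation), with the peroxidase PRDX1 at 370 ± 64.2 against 707 ± 262 FPKM and SOD2 at 111 ± 6.47 against 138 ± 25.5 FPKM. They were not called without control 3 (−0.03) or lactulose 2 (−0.17). Cell cycle genes fell (59 of 64 negative, adjusted p = 2.6e-12; adjusted p = 0.598 with an estimated correlation), with CENPK at −0.73 ± 0.23 and TK1 at −0.58 ± 0.20. Apoptosis genes fell (28 of 32 negative, median −0.16, adjusted p = 0.00056; adjusted p = 0.598 with an estimated correlation), with BCL2L15 at −1.37 ± 0.41. Their median was −0.08 without control 3 and −0.10 without lactulose 2. In these 5 lists 0 members passed adjusted over the list alone.

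T and NK cell genes fell (26 of 28 negative, adjusted p = 4.8e-06; adjusted p = 0.598 with an estimated correlation), and 0 passed adjusted over the list alone. CTLA4, the inhibitory T cell receptor, stood at 0.914 ± 0.202 against 2.02 ± 0.224 FPKM and CD4 at 9.38 ± 0.656 against 12.6 ± 3.57 FPKM. Without control 4 the list was not called (median −0.12). TLR, NF-kB and cytokine genes fell (31 of 44 negative, adjusted p = 0.00056; adjusted p = 0.598 with an estimated correlation), with a median of −0.08 and a mean of −0.29. Adjusted over the list alone 6 fell, against 0 over all genes by edgeR. They were the B cell factor TNFSF13B (5.83 ± 1.32 to 3.83 ± 0.484 FPKM), CCL20 (40.3 ± 12.8 to 20.1 ± 4.21 FPKM), the cytokines IL22 (5.53 ± 3.59 to 1.33 ± 1.22 FPKM) and IL26 (0.490 ± 0.302 to 0.152 ± 0.101 FPKM), NFKBIZ (24.2 ± 13.6 to 11.1 ± 2.97 FPKM) and the bacterial lipoprotein receptor TLR2 (10.4 ± 3.72 to 6.90 ± 0.645 FPKM). This list was not called without control 7 (median −0.01), and stood at −0.13 without control 4, −0.14 without control 6, −0.16 without lactulose 3 and −0.21 without lactulose 5.

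Smooth muscle genes rose (19 of 20 positive, adjusted p = 2.8e-07; adjusted p = 0.598 with an estimated correlation), with LMOD1 and FLNC at 0.72 ± 0.24 and 0.33 ± 0.14, and their median was 0.25 without lactulose 2. Collagen and matrix genes rose (31 of 35 positive, median 0.28, adjusted p = 4.2e-05; adjusted p = 0.687 with an estimated correlation), with LOXL1 and LAMA4 at 0.46 ± 0.22 and 0.43 ± 0.25. That list was not called without control 3 (0.06) or lactulose 2 (0.10), and stood at 0.46 without control 6. Endothelium genes rose (14 of 17 positive, median 0.12, adjusted p = 0.018; adjusted p = 0.721 with an estimated correlation), with FLT1 and TEK at 0.76 ± 0.30 and 0.55 ± 0.32. They were not called without control 3, 4 or 7 or lactulose 2 or 6 (medians 0.03 to 0.16), and stood at 0.37 without control 6 and 0.19 without lactulose 3 or 5. Enteric neuron and glia genes rose (18 of 22 positive, median 0.27, adjusted p = 0.015; adjusted p = 0.687 with an estimated correlation), with GFRA3 and SYT1 at 0.54 ± 0.30 and 0.65 ± 0.41. They were not called without control 3 (0.19), control 4 (0.21) or lactulose 2 (0.13), and stood at 0.53 without control 6. In these 4 lists 0 members passed adjusted over the list alone.

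Enteroendocrine genes rose (13 of 17 positive, median 0.34, adjusted p = 0.0016; adjusted p = 0.598 with an estimated correlation), and CHGA and INSM1, a transcription factor of endocrine cells (1.95 ± 0.494 to 3.74 ± 0.665 FPKM), rose adjusted over the list alone. The list was not called without control 6 (0.33). Immediate early genes rose (23 of 28 positive, median 0.35, adjusted p = 0.0080; adjusted p = 0.598 with an estimated correlation), with KLF10 and BTG2 at 0.54 ± 0.19 and 0.59 ± 0.22. They were not called without control 4 (0.25), control 6 (0.21) or lactulose 6 (0.20). Carbohydrate digestion and hexose uptake genes rose (14 of 17 positive, median 0.34, adjusted p = 0.041; adjusted p = 0.687 with an estimated correlation), with the glucose transporters SLC2A2 at 37.5 ± 41.7 against 3.05 ± 2.46 FPKM and SLC2A1 at 12.4 ± 2.45 against 9.31 ± 3.07 FPKM. The SLC2A2 mean came from the near-alike lactulose 3 and 5 (70.8 and 76.3 FPKM), while lactulose 2 and 6 had 0.687 and 2.27 FPKM. They were not called without control 6 (0.24) or 7 (0.39) or lactulose 3 (0.25) or 5 (0.13), nor by limma on log2 FPKM (0.25 and 0.23), with lactulose 3 and 5 as 1 library (0.19), without both libraries in doubt (0.24) or with counts divided by 4 (0.21). The same held with the enterocyte level as a covariate (median 0.10, adjusted p = 0.0755, in a range of 2.7e-05 to 0.569 over 17 alternatives). In both of these lists 0 members passed adjusted over the list alone.

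Genes moved by high protein and back by lactulose were counted as the design foresaw. By edgeR 0 genes were called in both comparisons with opposite signs, and 127 were at an unadjusted p under 0.05 in both, 37 higher then lower and 90 lower then higher. Independent lists would give 7.04 and 6.92, but both comparisons use the high protein libraries with opposite sign. Among 100 groupings of the 12 libraries, the real one included, 40 had at least 127 such genes, and the others had a median of 90 and a highest count of 1233. Across genes, which are not independent replicates, the log2 fold changes correlated at −0.44, where 100 simulations without effect gave a median of −0.51 (central 95% of them, −0.76 to 0.05), and 70 of them were as low. The covariance was −0.0752, against −0.0929 in the simulations. With the high protein libraries split between the comparisons, the 6 correlations ran from −0.10 to 0.16.

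Uric acid is the end product of nitrogen metabolism in birds, and the title of the series names it. Genes of uric acid and purine breakdown were not called in any comparison (24 members, adjusted p = 0.654, 0.773 and 0.875), nor were urate transporters (7 members, adjusted p = 0.959, 0.542 and 0.444). XDH, which makes uric acid, stood at 14.9 ± 5.85 FPKM in controls, 13.1 ± 5.04 with high protein and 16.6 ± 8.31 with lactulose. ADA, which deaminates adenosine, stood at 31.8 ± 18.7, 30.1 ± 16.3 and 37.6 ± 15.2 FPKM in the same order. The urate transporter SLC2A9 stood at 6.59 ± 2.40, 6.18 ± 1.65 and 6.55 ± 2.03 FPKM, the exporter ABCG2 at 18.0 ± 7.02, 24.03 ± 13.9 and 32.4 ± 19.0 FPKM, and ABCC4 at 3.37 ± 1.22, 3.21 ± 0.607 and 3.95 ± 0.567 FPKM. The differences of these 5 genes lay within the spread between libraries, with edgeR adjusted p of 0.798 or more in each comparison.

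Barrier and sensing genes also stayed short of the threshold. In controls, high protein and lactulose in turn, the junction protein OCLN stood at 25.2 ± 6.02, 20.8 ± 4.42 and 29.8 ± 9.45 FPKM and CLDN1 at 17.3 ± 7.17, 10.1 ± 2.12 and 13.6 ± 3.38 FPKM. TJP1 stood at 3.11 ± 1.02, 3.18 ± 0.384 and 3.72 ± 0.559 FPKM, and the gel-forming mucin MUC2 at 2.45 ± 2.06, 1.92 ± 0.741 and 4.39 ± 1.67 FPKM. The lipopolysaccharide receptor TLR4 stood at 1.02 ± 0.351, 1.32 ± 0.153 and 1.23 ± 0.0738 FPKM, its adaptor MYD88 at 22.0 ± 5.48, 23.8 ± 3.35 and 22.8 ± 0.709 FPKM, and NFKB1 at 27.3 ± 8.90, 27.7 ± 3.28 and 26.9 ± 2.497 FPKM. IL6 was near its floor, at 0.0729 ± 0.0517, 0.0750 ± 0.0269 and 0.106 ± 0.0883 FPKM. The peptide transporter SLC15A1 stood at 340 ± 142, 367 ± 206 and 318 ± 248 FPKM.

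In all, 20 of the 43 lists were called in no comparison. In the order of the 3 comparisons, adjusted p was 0.0600, 0.378 and 0.425 for lipid absorption and lipoproteins, in which SCARB1 rose adjusted over the list alone in the first and the third. It was 0.0640, 0.574 and 0.381 for mucosal antimicrobial defence (1 member fell adjusted over the list alone in the third), 0.214, 0.0788 and 0.633 for mucus and goblet cells, 0.192, 0.758 and 0.348 for interferon-stimulated genes, and 0.474, 0.0843 and 0.401 for enterocytes. Fibroblast markers, at 0.959, 0.0575 and 0.128, had the lowest value of the uncalled lists. Exocrine pancreas markers, at 0.976, 0.188 and 0.236, held CEL, which fell adjusted over the list alone in the second and the third comparisons. The remaining lists held amino acid breakdown, ATF4 targets, cholesterol synthesis, short-chain fatty acid sensing, the unfolded protein response, xenobiotic metabolism, crypt stem cells, distal gut position, liver, red blood cells and thrombocytes, and epithelium of other organs. Their adjusted p lay between 0.102 and 0.960. In 20 of 90 uncalled tests and 0 called ones, median, mean and test differed in sign.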

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

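Tests chosen only after the result was seen were, for the near-alike lactulose libraries, the W-linked share and the count of lists with the pair as 1 library. For the ribosomal protein lists they were the pair, scaling and diet tests, and for the macrophage list all tests.

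Within a group of 4, a library was picked out when its gap to the nearest other library exceeded Dixon's 95% critical share of the group's range. This held in 25 of 362 groups (6.91%), where chance gives about 1 in 20 for 4 independent values. Lactulose 3 and 5 were nearly alike, so lactulose 2 and 6 are picked out more easily than that. Of the 25, 8 were in lactulose 2, 4 in lactulose 6 and 3 in control 3. Lactulose 2 was highest in its group for the cell cycle score (0.880 of the range), BUB1 (0.892), TK1 (0.835), CD4 (0.899), TNFSF13B (0.938), SLC38A1 (0.881), GMPS (0.831) and WDR31 (0.837). Lactulose 6 was highest for the ribosomal protein score (0.851) and RPS27A (0.855; 1576 FPKM against 818 to 928), and lowest for ABCC4 (0.912; 3.10 against 4.17 to 4.27 FPKM) and CP (0.936). Lactulose 3 was lowest for HSF1 (0.893). Control 3 was highest for NDUFV2 (0.879; 276 FPKM against 116 to 136) and lowest for NFKB1 (0.875; 14.0 against 30.4 to 32.8 FPKM) and the de novo purine score (0.859). Control 4 was highest for the T and NK cell score (0.912), control 6 for NMRAL1 (0.867) and control 7 for LCT (0.875). High protein 1 was highest for GATA4 (0.983; 4.07 FPKM against 0 to 0.0700) and LCT (0.944; 6.91 FPKM against 0.176 to 0.555). High protein 3 was highest for LOXL1 (0.984) and NID1 (0.873), high protein 4 for IL26 (0.847) and high protein 5 for DUSP1 (0.913).

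Lactulose 3 and 5 were nearly alike, and 9 W-linked genes (the W is the female sex chromosome of birds) stood between the levels of lactulose 5 and 6 in lactulose 3, such as LOC125179667 with 45, 409 and 3837 counts in lactulose 5, 3 and 6. These 9 were picked for high counts in lactulose 6 and under 0.05 of its level in lactulose 5. Some other W-linked genes did not lie between, such as LOC125181591 with 12, 0 and 46 counts and LOC106049344 with 18176, 18718 and 10683. A candidate explanation is that lactulose 3 holds lactulose 5 with a share of lactulose 6, estimated at 0.0846 (0.0514 to 0.106 over the 9 genes). A fit over genes not placed on W, with all other libraries as parts, gave 0.888 for lactulose 5 and 0.0856 for lactulose 6. The next largest coefficient was 0.0141, for control 3. Read-pair noise alone is argued against as the rest. After the mixture was taken out, the squared difference per count above 10000 counts, scaled as before, was 14.1, against about 4 for that noise. But the 17 other pairs within groups had 336 to 3764, so whether the rest is of a separate sample stays open. With the pair as 1 library, 12 of the 16 lists of lactulose against high protein were still called, which argues against the pair alone making those 12. The lists no longer called were peptide and amino acid absorption (median 0.13), bile acid handling (0.17), junction genes (0.09) and cell cycle genes (−0.04), so for these the pair stays open.

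Ribosomal protein and oxidative phosphorylation genes were lower with lactulose, though not with an estimated correlation (adjusted p = 0.410 and 0.640 by camera). The tables argue against the near-alike pair as the whole cause (ribosomal median −0.72 with the pair as 1 library), while median-of-ratios scaling (−0.78) moved this list only as it moved all genes and so does not test scaling. A bias against short, abundant transcripts stays open: the 32 other genes nearest in length and level had a median of −0.12 (95% bootstrap interval −0.24 to 0.03), but their level was lower (a median of −0.69 log2 relative to the ribosomal genes), so they test abundance poorly. Diet also stays open, with an exact permutation p of 0.0571 for the ribosomal score. Against controls the ribosomal median was −0.23 without control 3.

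Macrophage and dendritic cell genes were higher with high protein and lower with lactulose, and neither call held with an estimated correlation (adjusted p = 0.391 and 0.0894 by camera). The tables argue, but only weakly, against a lower share of epithelium in the high protein libraries as the whole cause. With the enterocyte level as a covariate, this list stayed called at the preset correlation with medians of 0.25 and −0.38. The covariate ended the call of bile acid handling, but that list was near the threshold. More lists were called with it (11 for high protein against control, 18 for lactulose against high protein) than by the main fit (9 and 16). A kept call therefore shows little. The macrophage score minus that of smooth muscle, lactulose against high protein, decided nothing (−0.39, exact permutation p of 0.200), and smooth muscle itself differed by 0.05. More leukocytes of all kinds would give a higher B and plasma cell score with high protein than in controls. That score was lower, by −0.34, but within the spread (exact permutation p = 0.314), and the mean T and NK cell score was not higher either. The macrophage score minus that of B and plasma cells, high protein against control, differed by 0.59 with an exact p of 0.0857. This explanation therefore stays open. For diet, the score differed between lactulose and high protein with an exact p of 0.0286, the smallest possible, and 0.527 adjusted over the lists.

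Other splits of the same libraries were counted for each comparison. At least the real number of lists was called by 26 of 35 splits in high protein against control (real 9, highest other 27), by 13 of 35 in lactulose against high protein (16; highest other 25) and by 14 of 35 in lactulose against control (14; highest other 24). Chance cannot be excluded for these counts of lists. For single genes the real count was 0, which every split reaches (35 of 35 in each comparison, and 100 of 100 groupings for genes moved by high protein and back by lactulose), so those counts test nothing. The highest other counts of genes were 46, 1 and 9 in the 3 comparisons and 0 for the genes moved and moved back. The split of control 3 and 4 with high protein 3 and 5 against the rest called the 46 genes, and that of control 3 and 4 with lactulose 3 and 5 the 9 genes. Both part libraries with low from libraries with high W-linked counts. LOC125179667 had 12 to 86 counts in control 3 and 4, high protein 3 and 5 and lactulose 5, and 409 in lactulose 3. Elsewhere it had 3357 to 4294, so the libraries part as samples of both sexes would. Lactulose 3 and 5 against lactulose 2 and 6, as given above for FOS, DUSP1, SLC1A1, SLC10A2 and SLC2A2, is the same split. Within the controls and within high protein, libraries with low and with high W-linked counts overlapped for FOS, SLC1A1 and SLC10A2. DUSP1 and SLC2A2 parted in controls as they did with lactulose, but not so with high protein. With the W-linked score as a covariate, 0 genes and 11, 16 and 14 lists were called in the 3 comparisons. That fit compares diets and does not test these differences within lactulose. Sex was not tested as the cause of those differences.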

How the results depend on the processing

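The alternatives chosen only after the data were seen were counts divided by 4, lactulose 3 and 5 as 1 library, both libraries in doubt left out, the W-linked and enterocyte covariates, and limma on log2(FPKM + 1). By edgeR 0 genes were called in each comparison. DESeq2 called 8 genes for high protein against control, 19 for lactulose against high protein and 22 for lactulose against control. For high protein against control and for lactulose against control, limma called 1 gene with a pseudocount of 0.1 and 1 with a pseudocount of 1, edgeR without a filter called 1, and leaving out 1 library of the groups compared gave 0 to 1. Leaving out a library of the group not compared gave 1 gene for lactulose against high protein without control 7 and 1 for lactulose against control without high protein 5. Sample weights called 513 genes for lactulose against high protein and 0 for the other comparisons. An unadjusted p under 0.05 with at least a 2-fold change gave 179, 206 and 233 genes. Genes moved by high protein and back by lactulose numbered 127 at an unadjusted p under 0.05 in both comparisons, whatever the fold change. Of the 9, 16 and 14 called lists, 0, 0 and 0 were called by camera with an estimated correlation and 0, 2 and 0 by fry. With the replicate block, which took the replicate number as a term, 0 genes were called in each comparison and 11, 22 and 11 lists. Libraries that share a number correlated only at −0.13 to 0.20, on another scale than the correlations across genes given above. On that earlier scale the same pairs had 0.949 to 0.982. Filters, quantile normalization, sample weights and only the groups compared called 7 to 16, 13 to 20 and 8 to 16 lists. They were not followed list by list. Over the other alternatives, the 39 called list results gave 741 values. Of these, 535 kept the call, 202 kept the direction of the list test without passing and 4 took the other direction in that test. The last were collagen and matrix genes for high protein against control (−0.12 without control 3, −0.12 to 0.28 over the left-out libraries, and −0.12 without both libraries in doubt) and enteric neuron and glia genes with the replicate block (−0.11 for lactulose against high protein and 0.038 for lactulose against control, where the median kept its sign and the test did not). Whatever the test, 11 list medians took the other sign, and 2 of these lists were still called. Beside those given, they were collagen and endothelium genes for high protein against control without high protein 3 (−0.03 and −0.01), cell cycle genes for lactulose against high protein by limma (0.0094 and 0.0075), antioxidant genes there with the replicate block (0.0056), and TLR, NF-kB and cytokine genes for lactulose against control. The TLR medians were 0.03 and 0.02 by limma, whose list test still called them lower, and 0.05 with the replicate block. Of 3267 values of named genes, 41 were past the threshold and 99 had the other sign without passing it. Apart from left-out libraries, limma with both pseudocounts ended the calls of B and plasma cell, collagen and proximal genes for high protein against control, of apoptosis, cell cycle, neuron and glia, bile acid and peptide absorption genes for lactulose against high protein, and of carbohydrate, endothelium and neuron and glia genes for lactulose against control. In the same order of comparisons, the replicate block ended those of B and plasma cell, immediate early and proximal genes, of T and NK cell, antioxidant, apoptosis, neuron and glia and oxidative phosphorylation genes, and of T and NK cell, TLR, antioxidant, apoptosis, collagen, endothelium, neuron and glia, enteroendocrine and smooth muscle genes. Leaving out both libraries in doubt ended those of collagen, endothelium and heat shock genes, of cell cycle, purine, bile acid, peptide absorption and junction genes, and of antioxidant, carbohydrate, collagen, endothelium, neuron and glia and oxidative phosphorylation genes. Counts divided by 4 ended those of proximal genes in the first comparison and carbohydrate genes in the last. The cause was not tested for any of these differences.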

Other observations

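Tests chosen only after the result was seen were those of RARB and of the single clock genes. ISX and SCARB1 were picked because they differed between the controls and the other libraries, so no test of that difference is given. Transcripts absent from controls were picked after their values were seen.

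ISX was lower in both groups on the higher protein diet, and SCARB1 higher. Over the 8 libraries against the 4 controls the log2 CPM difference was −1.35 for ISX and 2.32 for SCARB1, and neither gene passed edgeR over all genes, while DESeq2 called both. In mice, ISX represses SCARB1 and the carotenoid-cleaving enzyme BCO1, so a hypothesis is that genes repressed by ISX are higher where ISX is lower. BCO1 did not separate the groups (difference 0.40, exact p = 0.277), and high protein 1 held the highest SCARB1 and BCO1 levels (74.5 and 17.5 FPKM). Lower retinoic acid signalling was tested as another hypothesis, and 4 genes induced by retinoic acid had an exact p of 0.713, with RARB alone lower by −0.43 (exact p = 0.0283). Of these 4, CYP26A1 and CYP26B1 were near the floor, at no more than 0.177 and 0.280 FPKM in any library. The mean of the 4 could therefore hardly show a change. Both hypotheses stay open.

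Clock and immediate early genes were higher with lactulose than with high protein alone, though neither list was called with an estimated correlation (adjusted p = 0.406 and 0.0645 by camera). On the log2 scale PER2 was higher by 0.65, PER3 by 0.74 and JUN by 0.52 (exact permutation p = 0.0286 each, for genes picked because they were higher). FOS and NR1D2 had an exact p of 0.0857 each, and BHLHE40 one of 0.314. If the clock stood at another phase at sampling, CLOCK, NPAS2 and ARNTL would move opposite to the period genes. Their mean difference was −0.10 (exact p = 0.629), with CLOCK itself higher by 0.30, so this stays open, and the labels used here give no sampling time.

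LOC125183064 (ID 125183064; NW_025927697.1, 4713963 to 4714251) and LOC106029782 (ID 106029782; NW_025927777.1, 1920151 to 1953445), both long non-coding RNAs, had 0 counts in all 4 controls and counts in all 8 other libraries. Against a floor of 3 counts per library, LOC125183064 stood 78.6-fold higher with high protein and 59.7-fold higher with lactulose. LOC106029782 stood 4.11-fold and 3.21-fold higher in the same order. These folds are no lower bounds, because the floor lies below the counts that a read pair stands for. Of the 495 choices of 4 libraries, 26 had at least the real 2 such genes, with a highest other of 4, so chance zeros cannot be excluded for such genes as a class. That count admits genes with as few as 4 counts in a library and says little about LOC125183064, which had at least 74. Over all genes, LOC125183064 missed the threshold by edgeR and was called by DESeq2, by limma on log2 FPKM and by edgeR without a filter, in both comparisons with control.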
